A study of Mus musculus with 3 samples.

How the data were processed

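RNA from papillomas of wild-type, Lgals7-/- and Tg46 mice was extracted with TRIzol and RNeasy columns, 3 tumours pooled per genotype, and made into libraries with an Illumina RNA sample preparation kit, per the labels' protocols. The deposited values are whole-number read counts per Entrez gene identifier for 3 libraries, and the build named in the submitters' processing notes is mm10. The aligner, the counting tool, its annotation and whether it used strand are not given in the sources used here. Of 24028 identifiers, 23968 matched a RefSeq symbol (GRCm38 annotation), 60 did not, 23711 matched a GENCODE gene model and 946 held 0 counts in every library. Positions, exon overlaps and strands come from that annotation and not from the deposited counts.

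Total counts were 172011 in wild-type, 312600 in Lgals7-/- and 354499 in Tg46. Counts were scaled with edgeR 4.0.16 TMM factors (1.00, 1.05 and 0.945) in R 4.3.3. Genes with at least 10 counts in at least 1 library (12940 genes) were compared. Each ratio had 0.5 counts added to each library, except those of Lgals7 and of the summed hair keratin-associated protein genes. The 95% interval of each ratio is the exact Clopper-Pearson interval of the pair of counts. A gene was called higher or lower where the ratio was at least 2-fold and the interval excluded 1. With 1 library per genotype no quasi-likelihood test can be fitted and no p-values are given; a call compares 2 libraries, not conditions. Where a library held 0 counts, the fold is a lower bound against a floor of 3 counts per library, and no fold is given where both libraries are at or under it. This bound takes the other library's count as exact and can lie above the lower end of the 95% interval. For Lce1a1 in Lgals7-/- over wild-type these are 2.27 and 1.60.

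For 47 gene lists, the median log2 ratio of the measured members was placed among 10000 random lists of the same size drawn from 20 bins of abundance, and a list stood apart below percentile 2.5 or above 97.5. For lists that stood apart in at least 1 comparison, medians were also computed with genes at 0 in a library set to that floor, and are given where they differ. These lists, the comparisons and the rule for named genes were fixed before the data were examined. The set of chemosensory receptor genes was chosen afterwards and was not placed among random lists. The rule took Lgals7, then the 10 genes highest and the 10 lowest by the interval bound nearest 1 among called genes, without symbols of the form Gm plus digits or ending in Rik, then up to 4 called members with the largest absolute log2 ratio in each list described. For genes named by this rule that have an opposite-strand exon overlap the gene across is given. Their ratios are uncertain, and with the use of strand unknown those of other genes are ratios of the counts listed, which may not follow the gene's own transcript. The overlap of both comparisons with wild-type was set beside independent lists and beside 100 simulated draws of unchanged libraries. Intervals and ratios were tested on simulated data with 200 genes changed by known folds, drawn among genes expected at 10 counts or more. With counting error alone, 96.9%, 96.6% and 95.8% of intervals held the true ratio in Lgals7-/- over wild-type, Tg46 over wild-type and Tg46 over Lgals7-/-. With an assumed 40% variation between libraries, 78.5%, 78.2% and 69.7% did. That simulation and another at 10 times the depth were added after the data had been seen.

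Alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile factors, no filter, a filter of 100 counts, 5 added counts, fold alone, intervals wholly beyond 2-fold, a 4-fold threshold, totals without the 50 most abundant genes and list means. Chosen after seeing the data were libraries thinned to the smallest total, genes with no opposite-strand exon and the hair follicle list without Tchh. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.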

Results

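The libraries came from skin papillomas, benign epidermal tumours, raised in C57BL/6 mice with a carcinogen (DMBA) followed by a tumour promoter (TPA). One library was made per genotype, each from 3 pooled tumours. The genotypes were wild-type, Lgals7-/- (lacking galectin-7, a lectin of stratified epithelia) and Tg46 (a transgene expressing galectin-7 from the keratin 14 promoter). The comparisons ask how the tumour transcriptome differs with the presence and the amount of galectin-7. The deposited read counts summed to 172011 in wild-type, 312600 in Lgals7-/- and 354499 in Tg46, over 24028 gene identifiers. At least 10 counts were reached by 5541, 10041 and 9928 genes. These totals are low for a transcriptome, and a gene at 0 could lie at up to 17.4, 9.11 and 8.95 CPM (counts scaled to library size) in wild-type, Lgals7-/- and Tg46, the level of 3 counts. There is 1 library per genotype, so no difference below has a replicate check. The intervals of count ratios and the floors cover counting error only, since reads without molecular identifiers are not independent molecules.

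Lgals7 itself (Entrez 16858, chromosome 7, 28863853 to 28866284, plus strand, mm10) held 0 counts in wild-type, 2 in Lgals7-/- and 4 in Tg46. The ratio of Tg46 to Lgals7-/- was 1.96 (95% interval 0.282 to 21.7). These counts neither bear out the genotype labels nor go against them, and directions below are those of the libraries as labelled. Some transcripts found in every cell were also low. Gapdh, a glycolytic enzyme, held 0, 5 and 4 counts in wild-type, Lgals7-/- and Tg46. Actb, cytoplasmic actin, held 3, 13 and 13, and B2m, the MHC class I light chain, 0, 2 and 1. Some keratin genes of the epidermis ranked near the top, with 20, 81 and 95 counts at Krt14, 21, 132 and 156 at Krt1 and 25, 96 and 111 at Krt10, at percentile 92.6 of all identifiers or above in every library. Krt5, a basal keratin, held 7, 20 and 32, at percentiles 65.8, 82.1 and 91.6. Of the 100 genes with the most counts, 80, 78 and 83 in wild-type, Lgals7-/- and Tg46 had an exon overlapping an exon on the opposite strand, against 24.4% of the 23711 annotated genes. Tsix held 591, 1185 and 1084 counts, and Xist, which lies across it on the other strand, 106, 156 and 97. Syn3 held 410, 1608 and 878 counts and Timp3, across it, 15, 18 and 13. These example genes were chosen after their values were seen. Whether the counting used strand is not given in the sources used here, so the counts cannot be assigned to a strand, with or without such an overlap. Ratios and medians below are those of the counts listed at each gene, genes with an overlap included, and whether they follow the gene's own transcript is open.

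In Lgals7-/- relative to wild-type, genes of the cornified envelope and late keratinocyte differentiation were higher as a group, and genes of the type I interferon response were lower. Of 32 measured cornified envelope genes, 7 were called higher, 2 lower and 23 neither. Their median log2 ratio of 0.90 lay above those of 10000 random lists matched on abundance (percentile 100). Lce1a1, a late cornified envelope gene, was at least 2.27-fold higher, with 13 counts against 0. Kprp was 4.72-fold higher (1.02 to 290.0), whereas Sprr1a was 6.99-fold lower (2.46 to 31.3) and Krtdap 6.48-fold lower (1.52 to 73.7). Of 23 type I interferon genes, 2 were called higher, 10 lower and 11 neither, with a median of -1.01 (percentile 0.10). Oasl1, whose exons overlap those of Gm13822, was 5.72-fold lower (1.64 to 35.9) and Ifit1 4.33-fold lower (1.499 to 16.6). Against the group, Mx2 was at least 3.50-fold higher, with 20 counts against 0, and Irf7 was 6.82-fold higher (1.59 to 414), with an overlap with Phrf1. The 1439 chemosensory receptor genes, a set chosen after the data had been seen, stood at 3.21 CPM per kb of exon in wild-type and 2.52 in Lgals7-/-. Whether these counts are expression or background was not tested. If all annotated genes held as many per kb of exon, that would be 32.1%, 26.4% and 21.9% of the counts in wild-type, Lgals7-/- and Tg46. Of the 126 of them tested, 52 were called lower (41.3%) and 25 higher (19.8%), against 13.7% and 13.3% of all genes tested, with a median of -0.44. Here and in the other comparisons, a receptor gene or a list member could pass the filter through a high count in 1 library, which also favours a call. Oasl1 and Ifit1, for example, held 10 and 12 counts in wild-type against 3 and 5 in Lgals7-/-. The random lists were drawn from genes under the same filter. The shares of all genes are not matched on abundance. With 5 counts added the cornified envelope median was 0.33 (percentile 100), over the 5 members with 100 counts it was 1.38, and the mean of the interferon genes was -0.58.

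Over all 12940 genes tested, 1715 were called higher in Lgals7-/- than in wild-type and 1772 lower. Psmd7, a proteasome subunit (chromosome 8, 107580381 to 107588464, minus strand, mm10), was 8.48-fold higher (5.27 to 15.5), from 16 counts to 266. Dkk2, a Wnt pathway modulator, was 14.4-fold higher (4.75 to 150), and Ripor2 and Ccdc80 were at least 6.47-fold and 5.07-fold higher, both at 0 counts in wild-type. Mrpl1, Arhgap20 (overlapping Arhgap20os), Galnt15, Glb1l (overlapping Ankzf1), Bend3 and Fam53b followed. Among the genes called lower, Cts3 was at least 19.1-fold lower and Cdh19, a cadherin of glial lineages, at least 16.5-fold lower, both at 0 counts in Lgals7-/-. Mir6236 was 11.6-fold lower (7.40 to 19.7). The others were Mettl18, Timm8a1, Efemp1, Csrp3, the taste receptor gene Tas2r102, the vomeronasal receptor gene Vmn2r74 and the olfactory receptor gene Olfr837. In data simulated with counting error alone and 200 genes changed by known folds, 2.66% of the unchanged genes were called in this comparison, and 93.9% of genes changed 4-fold were recovered. With an assumed 40% variation between libraries added, 18.6% of the unchanged genes were called.

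In Tg46 relative to wild-type, cornified envelope genes and genes of glycolysis and hypoxia were higher as groups, and type I interferon and interferon-gamma response genes were lower. Of the 32 cornified envelope genes, 12 were called higher, 1 lower and 19 neither (median log2 ratio 1.17, percentile 99.99). Lce1a1 was at least 2.75-fold higher, Cers3, a ceramide synthase of the skin barrier, 5.82-fold higher (2.13 to 33.9) and Sbsn 5.76-fold higher (2.55 to 20.1), whereas Sprr1a was 12.8-fold lower (3.65 to 139). Of 18 glycolysis and hypoxia genes, 5 were called higher, 2 lower and 11 neither (median 0.71, percentile 98.2). Pkm, a pyruvate kinase, was at least 2.75-fold higher, Vegfa, an angiogenic factor, 6.29-fold higher (1.96 to 66.8) and Slc16a3 5.33-fold higher (1.19 to 326). Car9, with an overlap with Gm12454, was 4.93-fold higher (1.78 to 28.9). In Lgals7-/- over wild-type the glycolysis list had 4 called higher and 3 lower and did not stand apart (median 0.57, percentile 94.96). Of 23 type I interferon genes, 0 were called higher, 9 lower and 14 neither (median -0.74, percentile 0.55). With the gene at 0 in 1 library set to its bound the median was -0.96. Ifi204 was 22.6-fold lower (5.17 to 1378), Ifi27l2a 5.47-fold lower (2.01 to 20.5) and Herc6 4.53-fold lower (1.86 to 13.4). Oasl1, with an overlap with Gm13822, was 8.15-fold lower (2.07 to 91.0). Of 15 interferon-gamma genes, 3 were called lower and 12 neither (median -0.96, percentile 1.20), among them Gbp6 at 5.82-fold lower (1.66 to 36.6), Serping1 at 3.43-fold lower (1.21 to 11.7) and Ido1 at 2.76-fold lower (1.11 to 7.43). In Lgals7-/- over wild-type 5 of these 15 were called lower and 10 neither, but the list did not stand apart (median -0.24, percentile 21.5). Chemosensory receptor genes stood at 2.33 CPM per kb in Tg46 against 3.21 in wild-type. Of the 126 tested, 57 were called lower (45.2%) and 5 higher (3.97%), against 13.9% and 13.7% of all genes, with a median of -1.27. With libraries thinned to equal totals, the glycolysis list (percentile 94.7), the type I interferon list (-1.38, percentile 3.58) and the interferon-gamma list (percentile 12.4) did not stand apart, nor did interferon-gamma without the filter on low counts (-0.29, percentile 20.2) or by its mean (-0.61, percentile 2.5). The cornified envelope median was 0.73 in thinned libraries, 0.35 with 5 counts added and 1.91 over the 5 members with 100 counts, its mean was 0.75, and glycolysis was 0.21 with 5 counts added and 1.37 with no opposite-strand exon, where type I interferon was -1.12.

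**Figure D1:**
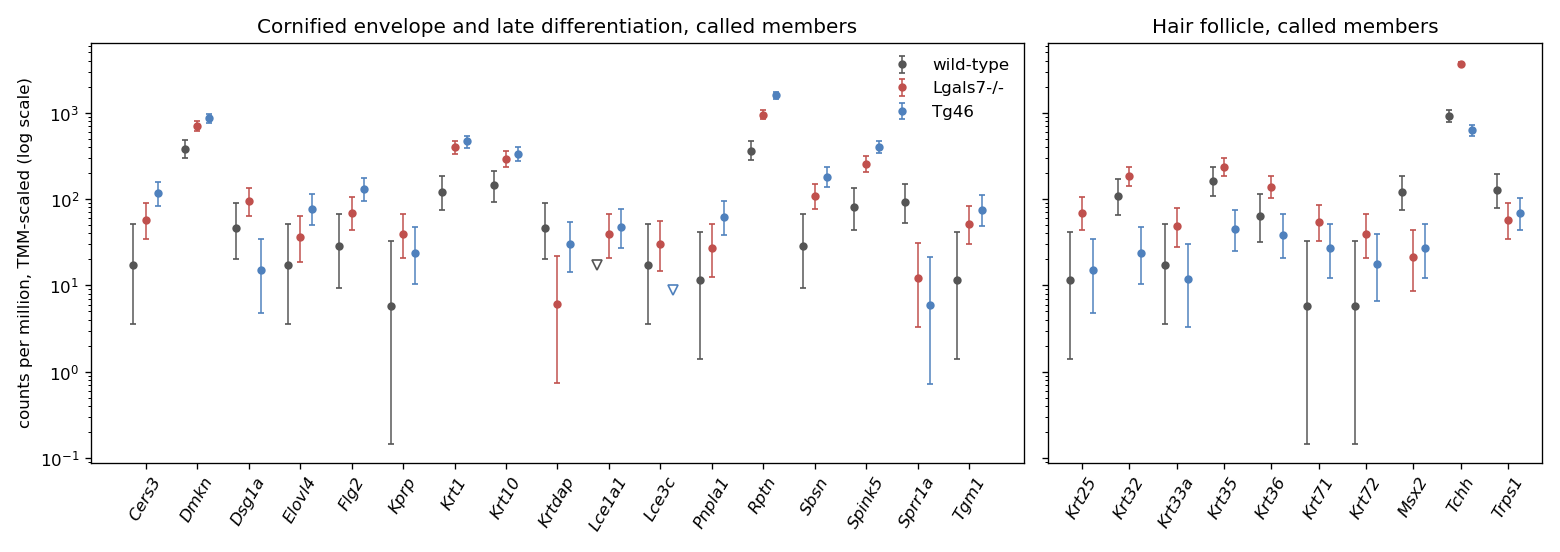
TMM-scaled CPM (log axis) of the 17 cornified envelope and 10 hair follicle genes called in at least 1 comparison, 1 library per genotype. Bars are exact 95% Poisson intervals and open triangles mark the level of 3 counts where a library held 0; Tchh stood at 1202 counts in Lgals7-/- against 160 in wild-type and 209 in Tg46.

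Over all genes, 1768 were called higher in Tg46 than in wild-type and 1793 lower. Primpol was 19.3-fold higher (6.45 to 201), with exons overlapping those of Cenpu. Psmd7 was 9.64-fold higher (6.01 to 17.6), Csta1, a cysteine protease inhibitor, 9.13-fold higher (4.78 to 22.8) and Fam221b 6.16-fold higher (4.59 to 8.63), the last with an overlap with Gm12481. Pthlh, the parathyroid hormone-related peptide, was at least 6.53-fold higher and Ccdc80 at least 8.08-fold higher. Comtd1 (overlapping A430057M04Rik), Fam53b, Dkk2 and Smim1 (overlapping Lrrc47) completed the list. Among those called lower, Nup35 and Ptpn22, a phosphatase of immune cells, were at least 11.6-fold and 10.99-fold lower, and Tmx4 was 13.9-fold lower (5.96 to 49.2). The rest were Pms1 (overlapping Gm28777), Timm8a1, Cts3, Mettl18, Psd4, Zim3 (overlapping Usp29) and Ppp1cb. In data simulated for this comparison, 2.96% of the unchanged genes were called with counting error alone and 19.3% with that variation added, and 73.9% of genes changed 4-fold were recovered with counting error alone.

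The calls of both comparisons against wild-type overlapped, with 788 genes higher in both and 1152 lower in both. Independent lists would share 234 and 246, and unchanged libraries set against the same wild-type library, simulated with 40% variation between libraries, shared 373 and 410. The covariance of the log2 ratios was 1.84, against 0.701 in that simulation. That simulation gave every library the same variation, and more variation in wild-type alone would raise both the shared calls and the covariance. The wild-type library cannot be split, so part or all of the excess may come from that shared library. The same limit holds for the cornified envelope and type I interferon lists, which moved the same way in both comparisons with wild-type. In Tg46 over Lgals7-/- neither stood apart (medians 0.20 and -0.37, percentiles 75.6 and 6.2). Across the tested genes, which are not independent replicates, the Spearman correlation was 0.613 between Tg46 and Lgals7-/-, 0.431 between Tg46 and wild-type and 0.420 between Lgals7-/- and wild-type. At equal totals these were 0.550, 0.410 and 0.402.

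In Tg46 relative to Lgals7-/-, hair follicle genes were lower as a group. Of 15 measured, 0 were called higher, 6 lower and 9 neither, and the median log2 ratio of -0.997 had percentile 0.015. Tchh, trichohyalin of the inner root sheath (chromosome 3, 93442330 to 93449077, mm10), was 5.84-fold lower (5.05 to 6.81), Krt35, a hair keratin, 5.16-fold lower (3.02 to 9.91) and Krt25 4.35-fold lower (1.74 to 15.8), and Krt32, with an overlap with Gm11571, was 7.37-fold lower (3.70 to 18.8). Against wild-type this list did not stand apart, with 5 called higher and 2 lower in Lgals7-/- (median 0.73, percentile 96.2) and 0 higher and 3 lower in Tg46 (median -0.59, percentile 3.16). Of 11 stress keratin and alarmin genes, 2 were called higher and 9 neither (median 0.79, percentile 98.7). Defb14, a beta-defensin, was at least 3.60-fold higher and Krt6a, with an overlap with Gm49428, 2.64-fold higher (1.79 to 4.05). Of 9 chemokine genes, 2 were called lower and 7 neither (median -1.07, percentile 1.54), namely Ccl3 at 8.48-fold lower (1.81 to 522) and Cxcl12 at 2.52-fold lower (1.25 to 5.77). Of 5 NK and cytotoxic cell genes, 2 were called lower and 3 neither (median -1.25, percentile 1.76), namely Klrb1c at 7.94-fold lower (2.33 to 85.6) and Klra7 at 3.64-fold lower (1.099 to 22.5). These 3 lists did not stand apart against wild-type, where in Lgals7-/- and Tg46 the stress keratin medians were 0.66 and 0.97 (percentiles 83.6 and 93.4), the chemokine medians 1.20 and 0.18 (80.9 and 29.8) and the NK medians 0.91 and -0.96 (73.4 and 5.83). With genes at 0 in a library set to the floor, the chemokine medians were 1.07 and -0.22, the second with its sign reversed. The stress keratin median in Lgals7-/- was then 0.55. Of the 126 chemosensory receptor genes, 29 were called lower (23%) and 9 higher (7.14%), against 7.73% and 8.43% of all genes, with a median of -0.65. Without the filter on low counts, of these lists only hair follicle stood apart, and the stress keratin median was -0.026 (percentile 58.9), the chemokine median -0.51 (percentile 2.75) and the NK median -0.19 (percentile 23.7). Stress keratins also did not stand apart over the 8 members with no opposite-strand exon (0.43, percentile 85.9) or in thinned libraries (percentile 97.4), chemokines in thinned libraries (percentile 7.98), or NK genes with 5 counts added (-0.76, percentile 2.63).

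Over all genes, 1091 were called higher in Tg46 than in Lgals7-/- and 1000 lower. Olfr510 was 24.2-fold higher (7.95 to 253), Adcy8, an adenylate cyclase, 8.75-fold higher (4.75 to 19.7) and Abi1, with an overlap with Pdss1, 6.58-fold higher (3.78 to 13.3). LTO1 was 4.98-fold higher (4.07 to 6.19), and its exons overlap those of Ccnd1, the cyclin D1 gene, on the other strand. Magel2, Iapp and Foxf1, the last overlapping Gm27530, were at least 5.89-fold, 6.22-fold and 5.57-fold higher, and Nrp, Atp5j (overlapping Gabpa) and Eme1 (overlapping Lrrc59) were the others. Besides the hair keratin genes and Tchh, Lyz1 was 9.16-fold lower (3.28 to 53.8), and Cdc20b, overlapping 4930563N14Rik, and Rdh16f2 were at least 5.43-fold and 5.09-fold lower. Platr4, Htatsf1, Zfp715 and Mpst were the rest. In data simulated for this comparison, 3.09% of the unchanged genes were called with counting error alone and 25% with 40% variation between libraries, and 91.7% of genes changed 4-fold were recovered with counting error alone. In the libraries themselves 8.43% of the genes tested were called higher and 7.73% lower. Together that is a smaller share than the 25% called among unchanged genes with the assumed variation.

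**Figure D2:**
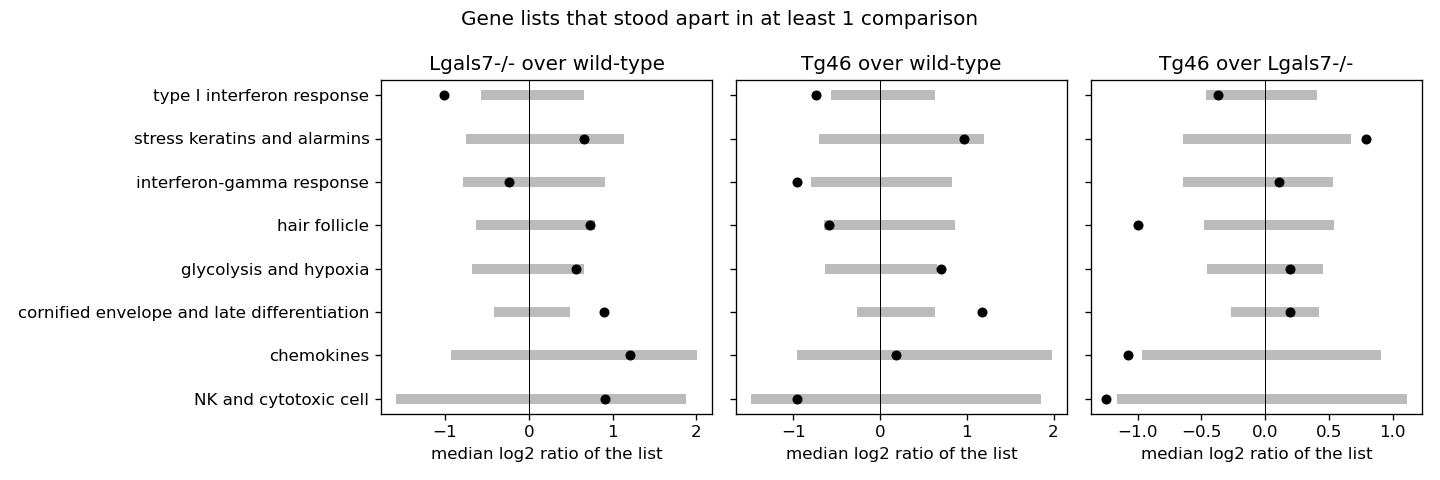
Median log2 ratio (points) of the gene lists that stood apart in at least 1 comparison, beside the central 95% of 10000 random lists matched on abundance (grey bars), 1 panel per comparison. The hair follicle list lies outside the random range in Tg46 over Lgals7-/- (-0.997). The cornified envelope list does so in both comparisons against wild-type (0.90 and 1.17), which share the wild-type library and are not independent.

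Of the 45 lists with enough measured members, 2, 4 and 4 stood apart from the central 95% of random lists in Lgals7-/- over wild-type, Tg46 over wild-type and Tg46 over Lgals7-/-, where chance alone gives 2.25 in each. The percentiles describe these libraries and are not tests of genotype.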

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

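No paired analysis was possible because each genotype has 1 library. Of 180 recomputed ratios of named genes, 167 stayed within their interval, 13 lay outside it with the same sign and 0 reversed. Of 92 recomputed list medians, 80 lay outside the central 95% of random lists and 1 reversed; those that did not stand apart are given with their comparisons, and the reversed one is stress keratins and alarmins in Tg46 over Lgals7-/-, at -0.026 without a filter, and the cause was not tested. Counts of calls are given in the order Lgals7-/- over wild-type, Tg46 over wild-type, Tg46 over Lgals7-/-. With a filter of 100 counts, which tests fewer genes, 31, 108 and 104 were higher, 20, 6 and 4 lower, and of the 2 lists that could be tested 1, 2 and 1 stood apart, 1, 1 and 0 of which also stood apart with the filter of 10 counts. Adding 5 counts left 584 and 658 higher against wild-type and gave 4 lists in Lgals7-/- over wild-type. Fold alone gave 3269, 3307 and 1808 higher and 1653 lower in Tg46 over Lgals7-/-. Intervals wholly beyond 2-fold left 235, 266 and 147 higher and 449, 449 and 86 lower. A 4-fold threshold gave 1134 and 325 higher in Tg46 over wild-type and over Lgals7-/-, 716, 763 and 309 lower, and 326 lower than wild-type in both. These are stricter or looser by construction. No filter left 1 list standing apart in Tg46 over Lgals7-/-, and the cause was not tested. Of the alternatives chosen after seeing the data, thinning to equal totals, with fewer counts, gave 1100, 902 and 470 higher. Of these, 879, 810 and 387 were also called at full depth. Thinning also gave 643 lower in Tg46 over Lgals7-/- (383 shared) and 2 lists there (1 shared), and 6 lists in Tg46 over wild-type (1 shared). In thinned libraries the NK list had too few members to test. Genes with no opposite-strand exon (8630 of 12940) left 1071 and 593 higher in Tg46 over wild-type and over Lgals7-/-, and 1377 and 745 lower. The loss was uneven, with 43.75% and 44.3% of calls higher instead of 49.6% and 52.2%. Among all genes called higher in Tg46, 38.6% and 44.8% had an opposite-strand exon, against 22.5% and 24.7% of those called lower. The cause was not tested. Upper-quartile factors shifted the median of all genes against wild-type by 0.21 and 0.24, so that 61.5% and 63.2% of calls were higher instead of 49.2% and 49.6%. Total counts shifted Tg46 over Lgals7-/- by -0.16 (35.6% instead of 52.2%), and thinning gave 36.4% in Tg46 over wild-type. Depth limits the recovery of 4-fold changes, at 93.9%, 73.9% and 91.7% in data simulated with counting error alone and 100% in each comparison at 10 times the depth. Recovery of 2-fold changes, which lie at the threshold, was 34.0%, 39.6% and 39.1%, and 48%, 40% and 50% at 10 times the depth.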

Other observations

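The tests of explanations in this part were chosen after the results they bear on had been seen. Intervals of list medians, of ratios of medians or variances and of correlation gaps in this part come from resampling genes (2000 draws, 200 for rank correlations). Those of percents are binomial over genes or pairs. Both treat genes of single libraries as independent, and show spread across genes rather than counting error or differences between animals.

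Macrophage markers fixed before the data were examined held more counts in Lgals7-/- than in Tg46 for Lyz2, at 39 against 6 (6.19-fold lower in Tg46, 2.78 to 19.1). Of the 10 monocyte and macrophage genes measured, 4 were called lower in Tg46 than in Lgals7-/- and 6 neither, where 7.73% of all genes were called lower. The median log2 ratio was -0.22 (percentile 21.7), so by its median the list did not stand apart. Its mean was further from 0, at -0.86. Against wild-type, 1 of them was called higher in Lgals7-/- (median 0.60, percentile 92.8) and 2 lower in Tg46 (median -0.36, percentile 16.2). Of 18 basal keratinocyte genes, 6 were called higher in Tg46 than in wild-type and 12 neither (median 0.50, percentile 94.6), and in Lgals7-/- over wild-type 3 were called higher, 3 lower and 12 neither (median 0.47, percentile 96.8).

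Housekeeping genes were low, with Gapdh and B2m near 0, and genes lying across other genes led the counts, although Krt1, Krt10, Krt14 and Col1a1 stood at percentile 92.6 of all identifiers or above in every library. Low depth alone is argued against, since 60% of the housekeeping genes (38.7 to 78.9) lay below the median protein-coding gene with a count, and depth thins all genes alike. This rests on an assumption, made after the data had been seen, that few housekeeping genes would otherwise lie below that median. The interval includes 50%. Gene coordinates of another build would ignore strand, yet median counts per kb were higher for opposite-strand than for same-strand overlaps in every library, by 1.19-fold at least (1.103 to 1.27). The share of such genes with 50 counts, which did not decide the point, differed by 2.58-fold at least. How the counting treated reads shared by genes on the same strand is not given, so these differences cannot exclude another build. Whether reads were assigned to the strand opposite the transcript was not settled. Of the 100 genes with the most counts, 80, 78 and 83 in wild-type, Lgals7-/- and Tg46 had an opposite-strand exon overlap, against 24.4% of annotated genes. For same-strand overlaps the numbers were 8, 13 and 10, against 8.1%. These values go with such an assignment. The test chosen to decide was the share of 26 pairs in which the gene across a listed gene held more counts, 69.2% (48.2 to 85.7). Its interval includes 50% and some overlaps are short, down to 9 bp, so it cannot exclude other causes. The kit as labelled is not stated to mark strand, so how such an assignment could arise is open, and no biological explanation was tested.

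The wild-type library stood apart from the others. Depth as the whole cause is argued against, since at equal totals the Spearman correlation of Tg46 with Lgals7-/- still exceeded the higher of those with wild-type by 0.140 (0.124 to 0.156). A candidate explanation is few starting molecules counted many times. At equal totals, counts of 1439 chemosensory receptor genes varied more around their length-scaled mean in wild-type. Their variance over Poisson was 1.86 times that of the higher of the others (1.44 to 2.22). Only Lgals7-/- and Tg46 were thinned. Their variance over Poisson was 5.50 and 5.31 before thinning and 3.69 and 3.31 after, against 6.88 in wild-type. Wild-type was highest either way, but the size of the ratio depends on thinning and does not decide the explanation. The genotype itself stays open, as untested with 1 library.

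Hair follicle genes were lower in Tg46 than in Lgals7-/-. Of the 15 members tested, 14 had no opposite-strand exon, with a median log2 ratio of -0.99 (-1.90 to -0.14). Exons annotated on the opposite strand are argued against as the whole cause for these 14, which lack them. Leaving out so few members could hardly move the median, which was -0.997 over all 15. The comparison therefore does not test whether reads were counted on the wrong strand. Members lying across an opposite-strand gene without an exon overlap were kept. Tchh lies across 1 such gene, so unspliced reads of such genes stay open as a cause. Whether the Lgals7-/- pool held more hair follicle tissue cannot be told apart from other causes: hair keratin-associated protein genes gave a ratio of Lgals7-/- over Tg46 of 1.22 (0.946 to 1.57) over all 52 of them, and of 1.31 (1.01 to 1.70) over the 50 outside the list. Both sets were computed because the first includes genes of the list, the choice decides whether the interval includes 1, and the counting intervals are too narrow where counts vary more than Poisson. Genotype stays open, as untested.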
